A study of Candida albicans with 5 samples.

How the data were processed

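Total RNA of untreated and sesamol-treated C. albicans SC5314 was copied into Cy3-labelled cRNA and hybridised to 5 arrays of a custom single-colour Agilent design, per the labels' protocols. The deposited scanner files hold an intensity per spot, made with Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes: the signal was background-subtracted and detrended within each array, and spots at background received a surrogate value. The files also give the mean signal and the local background as intensity values, per the file headers, with flags for spots well above background, saturated or outlying. The deposited series matrix holds the authors' processed values on what looks like a log2 scale, 1 value per gene ID for 6202 IDs. Each of its columns has a median of 0.73, its columns correlate with the log2 scanner values across genes at 0.985 to 0.991, and it was not centred on genes. Its log base and its normalization between arrays are read from the values only and stay unknown, and direction does not arise with a single colour.

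The test was limma's linear model on log2 of the processed signal. Control spots, 536 per array, were left out, spots with an outlier flag were set to missing, and saturated spots were kept. Spots of a probe were averaged. A probe counted as well above background on an array when at least 0.5 of its usable spots were. Each array was scaled by subtracting its 75th percentile over the 869 probes well above background on all arrays. The percentile was first planned over all non-control probes, and was changed because under 0.5 of the probes were detected; the planned form is given as an alternative. The subtracted values were 11.52 and 11.24 for the untreated arrays, 11.19 for sesamol replicate 1 and 10.39 and 11.43 for sesamol replicate 2. Probes were kept if well above background on every array of at least 1 group. Probes that match several gene IDs, 162 of 6302, were left out. Probes of 1 gene were averaged, which concerned 19 tested genes. In 6 of them the probes differed in sign, and in 1 by more than 2-fold. No called gene had probes of opposite sign.

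Arrays of the same group and replicate number were taken as repeats and averaged, which left 1 residual degree of freedom and a prior of 5.74 degrees of freedom. The lone untreated preparation was assumed to vary like the sesamol preparations. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided, and errors are limma's moderated SE with 2 sesamol preparations and 1 untreated preparation. For a gene not well above background on any array of a group, the bound is the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal among detected probes and the gene's own signal. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists tested, again with an estimated correlation, and with fry. All 5 arrays lay on 1 slide in 1 scan, so slide and scan were no batches.

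The scanner files give a gene ID, and as far as a cell of 255 characters reaches, an ORF number, an Assembly 21 location and a description. They give no gene symbols, and 0 IDs matched the reference table, so 41 lists planned by symbol could not be matched. In their place 53 lists were drawn from words of the descriptions, fixed before any difference between groups was looked at. Annotation lists repeat what the descriptions say of other experiments. Coordinates are printed where the cell held them. Of the 6040 genes, 1791 had a description that names a function.

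The text names the 12 largest rises and the 12 largest falls among called genes with a described function that were well above background in both groups on at least 1 array each and had all 3 sesamol arrays on 1 side of both untreated arrays. It also names up to 4 members of each called list that passed the test, a fixed set of antifungal target, efflux, calcineurin, iron and hyphal genes where measured, and the 4 largest bounds in each direction. The rule asked for a gene symbol, which was read as a description that names a function. These rules, the test and most alternatives were chosen before the data were examined, while the scaling was changed after the share of detected probes was seen.

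The procedure was tested on simulated data with 960 genes over 20 runs, with 200 genes changed and 20 more raised 1.5-fold as a list. For sesamol against untreated at the level of preparations it recovered 1.2% of genes changed 1.5-fold, 6.7% at 2-fold, 49.2% at 4-fold and 79.1% at 8-fold, and 7.9% of its calls were false. With the 5 arrays as separate samples the shares were 42.4%, 72.1%, 96.4% and 99.7%, and 42.6% of calls were false. Simulated repeats of a preparation lay closer together than the real ones, whose SD of the log2 difference was 0.38 for the untreated and 0.73 for the sesamol pair. The untreated preparation was also given the same spread as the sesamol ones. These shares, the 42.6% above all, may therefore not hold for the real arrays. A list of 20 genes raised 1.5-fold was called in 16 of 20 runs and an unchanged list in 0.

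Alternatives covered the background correction (normexp with an offset of 50), the scaling (quantile, median, all probes, cyclic loess), the filter, outlier spots, probes of a gene, the variance model, a test against a 1.5-fold change, the series matrix, what counts as a sample, and leaving out arrays and preparations. Computations used R 4.3.3 with limma 3.58.1, data.table version 1.17.8 and statmod 1.5.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.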

Results

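Transcript levels of Candida albicans, a yeast that lives on people and causes infections, were compared between cells grown with and without sesamol, a phenolic compound of sesame seed oil studied here for its antifungal effect. The strain was SC5314, the common laboratory reference of the species, grown at 30 °C, and the sesamol cultures received 4 mM of the compound until an OD600 of 1. The labels do not say at what density the untreated cultures were harvested, so a difference in growth stage between the groups is not excluded. Cy3-labelled RNA was hybridised to 5 single-colour Agilent arrays on 1 slide. The untreated group had 2 arrays, both of replicate 2, and the sesamol group had 3 arrays, 1 of replicate 1 and 2 of replicate 2. Arrays that shared a group and a replicate number were averaged, which left 1 untreated and 2 sesamol preparations. The titles carry the letters BR and TR, which the labels do not define, and no label states that the preparations came from separate cultures. The p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. On the 5 arrays, 2563 to 2894 of 15208 spots were well above background, or 16.85% to 19.03%. Of 6040 genes on the array, 1753 were well above background on at least 1 array, 811 were so on all 5, and 960 passed the filter and were tested.

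The first question was which genes differed between sesamol and untreated cells. In all, 79 genes changed, 32 upward and 47 downward. A gene counted as measured in both groups when it was well above background on at least 1 array of each. Among genes with a described function and measured in both groups, the largest rise was 7.03-fold, in a cytoplasmic protein of white-phase yeast cells, and the largest fall 7.92-fold, in a nucleoside transporter.

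CAL0000006, a putative hsp70 chaperone, rose 6.62-fold (log2 fold 2.73 ± 0.62, SE, limma adjusted p = 0.0476). Its log2 fold was 3.63 without sesamol replicate 1 and 1.89 without sesamol replicate 2, and its adjusted p was 0.407 with trend and robust. CAL0005613, described as a thioredoxin peroxidase, an enzyme that removes peroxides, rose 5.32-fold (log2 fold 2.41 ± 0.33, adjusted p = 0.0189), although only 1 of the 2 untreated arrays had it well above background. The heat-shock-like protein CAL0002694 (orf19.4526), on chromosome 1 from 411358 to 412386 on the forward strand in Assembly 21, rose 3.08-fold (log2 fold 1.62 ± 0.33). Of the 8 tested members of the heat shock and chaperone list, these 2 rose and 6 did not pass, with 2 rises and 1 fall when adjusted over the list alone. The list as a whole had a median log2 fold of -0.38 and an adjusted p of 0.787.

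CAL0003342, similar to the Wiskott-Aldrich syndrome protein and required for hyphal growth and polarized budding, rose 6.11-fold (log2 fold 2.61 ± 0.30, adjusted p = 0.00903). CAL0006153, the major exo-1,3-beta-glucanase, which cuts glucan of the wall, rose 3.20-fold, although only 1 of the 2 untreated arrays had it well above background, and a GPI-anchored cell wall protein, CAL0004519, rose 3.02-fold. CAL0000187, similar to the anchor subunit of alpha agglutinin, rose 3.04-fold. A protein kinase with a role in growth and morphogenesis, CAL0005438, rose 2.81-fold (log2 fold 1.49 ± 0.33). In the opposite direction, CAL0005117 (orf19.2837), a putative glucosyltransferase of mannan synthesis on chromosome R from 637555 to 638526 on the reverse strand, fell 5.56-fold (log2 fold -2.48 ± 0.37, but -1.38 with normexp) and was well above background on 2 of the 3 sesamol arrays. Of 34 tested genes for wall glucan, chitin and mannan, 2 rose and 1 fell over all genes, or 3 and 1 when adjusted over the list alone. That list had an adjusted p of 0.552.

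The white-phase protein CAF0006989 had a log2 fold of 2.81 ± 0.42 (adjusted p = 0.0239). CAL0004176, a counterpart of yeast Shr3p, which helps amino acid permeases leave the endoplasmic reticulum, rose 4.20-fold (log2 fold 2.07 ± 0.33, but 0.80 with normexp). Phosphoenolpyruvate carboxykinase, CAL0006389, the committed step of gluconeogenesis, rose 3.44-fold (log2 fold 1.78 ± 0.32). A high-affinity iron permease, CAL0003834, rose 2.79-fold (log2 fold 1.48 ± 0.30, adjusted p = 0.0376), and 1 of 9 tested genes for iron, copper and zinc uptake rose, by either adjustment, with an adjusted p of 0.657 for the list.

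The nucleoside transporter CAL0005596, which carries adenosine, uridine, inosine and guanosine with protons, had a log2 fold of -2.99 ± 0.30 (adjusted p = 0.00903). CAL0000766, similar to mitochondrial C1-tetrahydrofolate synthase, an enzyme of folate metabolism, fell 4.32-fold (log2 fold -2.11 ± 0.41). Ketol-acid reductoisomerase of the valine and isoleucine pathway, CAL0000685, fell 3.72-fold (log2 fold -1.90 ± 0.31). The arom enzyme of the aromatic pathway, CAL0004346 (orf19.4704, chromosome 4 from 159251 to 163906, forward strand), fell 2.75-fold, and homoaconitase of lysine synthesis, CAL0002066, fell 2.65-fold. The last was well above background on 2 of 3 sesamol arrays, and its adjusted p was 0.0873 with 5 separate arrays. Across 17 tested amino acid synthesis genes, 1 rose and 2 fell over all genes, and 2 rose and 3 fell when adjusted over the list alone. Their list had a median log2 fold of -0.43 and an adjusted p of 0.552. Arom and homoaconitase are not among the members of that list.

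CAL0004091, dUTP pyrophosphatase, which keeps uracil out of DNA, fell 3.66-fold (log2 fold -1.87 ± 0.32, adjusted p = 0.0298). CAL0001524, similar to the large subunit of ribonucleotide reductase, fell 3.58-fold (log2 fold -1.84 ± 0.31). A nucleolar protein, CAL0002295 (orf19.3138, chromosome 4 from 1497965 to 1498915, forward strand), fell 3.66-fold (log2 fold -1.87 ± 0.33). Lower values of a similar size were measured for CAL0004871, a putative lysyl-tRNA synthetase, which fell 3.27-fold, for CAL0003537, described as essential for growth, which fell 2.99-fold, and for CAL0001652, a transporter closest to a yeast vitamin B6 carrier, which fell 2.69-fold.

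**Figure D1:**
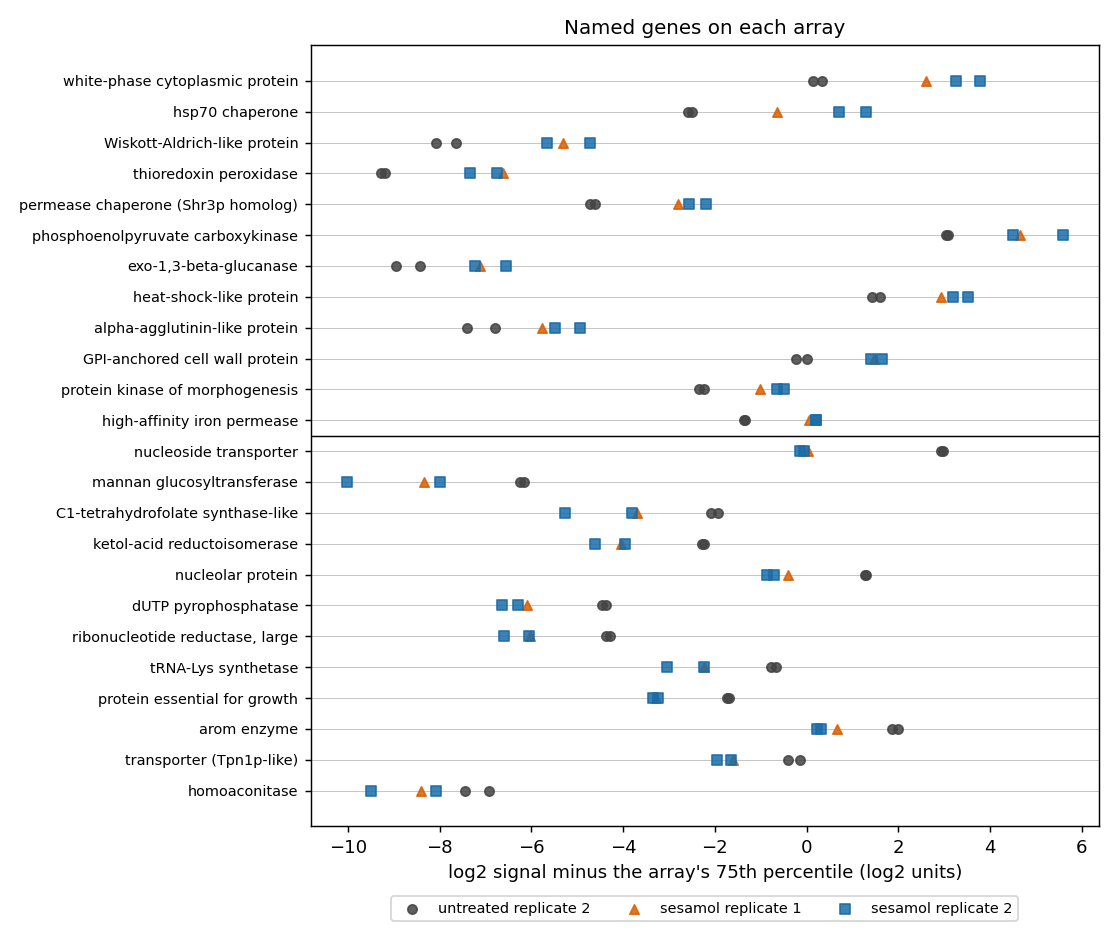
Level of the 12 largest rises (top) and 12 largest falls (bottom) among genes with a described function on each of the 5 arrays, as log2 signal minus the array's 75th percentile, so that 1 unit is a 2-fold difference. Each point is 1 array. All 3 sesamol arrays lie to the right of both untreated arrays for the rises and to the left for the falls, and the hsp70 chaperone has the widest gap between the sesamol preparations among the rises.

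Some genes were well above background in only 1 group, and for them the fold is given as a bound. It rests, per array of the dim group, on the higher of the lowest detected signal and the gene's own signal. Since a gene's own signal can lie above the lowest detected signal, the bound is not a strict limit. In sesamol cells, CAL0005303 (orf19.2124, chromosome 6 from 984557 to 985627, reverse strand), a predicted gene with no described function, was at least 9.19-fold higher (limma adjusted p = 0.00903), with a log2 fold of 2.80 without array 1 of the untreated replicate and 4.12 without its array 2. CAL0003683, induced by cadmium and regulated by Hog1p per its description, was at least 4.41-fold higher. CAL0000985, similar to D-xylulose reductase, stood 4.27-fold higher and the copper-binding metallothionein CAF0007466 3.16-fold. For CAL0000985 and CAF0007466 the gene's own signal set the value, so it is the plain fold and not a lower limit. The log2 fold of CAL0003683 was 2.65, but 3.26 without sesamol replicate 1 and 2.11 without replicate 2. CAF0007466 did not pass with 5 separate arrays (adjusted p = 0.0580), and the other tested metallothionein, CAF0007430, measured in both groups, had a log2 fold of 0.15 (adjusted p = 0.770). All 4 genes given as higher were not well above background in untreated cells. Not well above background in sesamol cells were CAL0000988, a putative nicotinic acid transporter at least 5.84-fold lower, CAL0002428, with no described function, at least 3.50-fold lower, CAL0005556 (orf19.4105) at least 3.08-fold lower and CAL0002562 (orf19.2591) at least 2.71-fold lower. The log2 fold of CAL0000988 was -2.65, but -1.32 with normexp. The log2 fold of CAL0005556 was -1.89, but it was -2.49 without array 1 of sesamol replicate 2, -1.33 without its array 2 and -3.79 with the series matrix values, and its adjusted p was 0.120 with 5 separate arrays. Of the 79 genes, 59 were measured in both groups, 8 were not well above background in untreated cells and 12 not in sesamol cells. Some of the 59 were well above background on only 1 array of a group. These include CAL0005613 and CAL0006153 in the untreated group and CAL0001783 in the sesamol group.

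Each of the 59 called genes measured in both groups differed at least 2-fold, and of the 20 with only a bound 18 had a bound of at least 2-fold. In each of the 79 the 3 sesamol arrays lay on 1 side of both untreated arrays. That separation held for 508 of the 960 tested genes, where chance would give 20% for 5 independent arrays. At the level of preparations, the untreated one lay outside both sesamol ones in 803 of the 960 genes, or 83.6%, where chance gives 66.7%. Over all 79 calls, with the plain fold taken for genes with only a bound, the smallest fold was 2.72 for rises and 2.44 for falls. An unadjusted p below 0.05 was found for 257 genes, where 48 were expected by chance. A peculiarity of the lone untreated preparation could raise this count and both shares above too, so the excess does not point to sesamol alone. Taking the 5 arrays as separate samples called 133 genes, 53 higher and 80 lower, of which 68 were among the 79. Without array 1 of sesamol replicate 2 the count was 7, without its array 2 it was 0 with 127 genes at an unadjusted p below 0.05, and without array 1 or array 2 of the untreated replicate it was 192 or 295. With normexp background correction the split was 36 higher and 610 lower and the median of all genes moved from 0.03 to -0.87. There the log2 folds of CAL0003342, CAL0005613, CAL0006153, CAL0000187 and all 4 named rises not well above background in untreated cells were negative, and the cause was not tested. With the 75th percentile taken over all probes the split was 45 higher and 119 lower around a median of -0.18.

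The genes most often asked about under antifungal compounds were mostly too dim to measure. Lanosterol 14-alpha-demethylase, C-5 sterol desaturase, squalene epoxidase, the multidrug transporters, the catalytic subunit of calcineurin, the transcription factor named with calcineurin, another high-affinity iron permease, CAL0003776, the ferric reductase of low-iron cells and the hyphal cell wall protein were well above background on 0 of the 5 arrays. The regulatory subunit of calcineurin was so on 1 array, in the untreated group. Of 20 ergosterol and isoprenoid genes, 2 could be tested and 0 passed by either adjustment, and 0 of 33 drug efflux transporters could be tested. Actin was saturated on 3 arrays and its spots were outliers on the others, so it was not tested.

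The second question was which groups of genes shifted as a group. By camera with its preset correlation, 5 of 36 tested lists passed. The lists with a lower median were the tRNA synthetases, the translation factors, the nucleotide synthesis genes and the genes lowered on phagocytosis, and the list with a higher median was the genes whose descriptions say that alkaline pH lowers them. With an estimated correlation the adjusted p of each of the 5 was 0.949 and 0 lists had an unadjusted p below 0.05. That form of the test ran on the 1 residual degree of freedom of the preparations. With 5 separate arrays, which leave 3 residual degrees of freedom, the adjusted p of each of the 5 was 0.934. How far that form can pass any list on so few degrees of freedom was not tested. The correlations estimated on the preparations ranged from -0.20 to 1.00, against the preset 0.01. They were 1.00 for the tRNA synthetases and for the nucleotide synthesis genes, and 0.378 for the genes lowered on phagocytosis. For the translation factors the estimate was 0.0294, and for the alkaline-lowered genes -0.0550. For the alkaline-lowered genes the estimate lay below the preset value, so a higher correlation cannot have removed that call. For the other called lists, whether the few degrees of freedom or the correlation removed the call stays open. The calls do not hold without the preset value. The rotation test fry called 0 of the 36, with 3 at an unadjusted p below 0.05. With normexp, camera called 7 lists, all 7 upward against the other genes, and 1 of them was among the 5, the alkaline-lowered genes, whose median there was -0.14.

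All 6 tested tRNA synthetases were lower in sesamol cells, with a median log2 fold of -1.13 (limma camera adjusted p = 0.0258, and adjusted p = 0.949 with an estimated correlation). The lysine enzyme CAL0004871 fell over all genes, with a log2 fold of -1.71 ± 0.33, and 4 members fell when adjusted over the list alone. The other 3 of these were the phenylalanine enzyme CAL0006075 at -1.16, the asparagine enzyme CAL0004700 at -1.15 and the serine enzyme CAL0004049 at -1.12, which charges the tRNA for the CUG codon that this yeast reads as serine. Over all genes these 3 did not pass (limma adjusted p of 0.074, 0.075 and 0.085). The list was singled out by the same values.

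Of 17 translation factors, 14 were lower and the median log2 fold was -0.75 (adjusted p = 0.0261, and adjusted p = 0.949 with an estimated correlation). CAL0001783, the counterpart of initiation factor eIF5B, fell 2.65-fold (log2 fold -1.40 ± 0.33) and was well above background on 1 of 3 sesamol arrays. It was the only member past the test over all genes, and 0 members passed when adjusted over the list alone. Of 47 cytosolic ribosomal proteins, 1 fell over all genes and 0 when adjusted over the list alone. Their median log2 fold was -0.17, with an adjusted p of 0.151, or 0.0388 with 5 separate arrays and 0.0170 without array 1 of sesamol replicate 2.

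The genes described as lowered when macrophages engulf the yeast had a median log2 fold of -0.31 over 48 tested members (adjusted p = 0.0138, and adjusted p = 0.949 with an estimated correlation). This list shares 5 members with the tRNA synthetases, 9 with the translation factors and 25 with the cytosolic ribosomal proteins, so it is not an independent result. The 9 members in none of these 3 lists had a median log2 fold of -0.36. Over all genes 3 members fell, and 2 when adjusted over the list alone. They were CAL0004871, CAL0001783 and CAL0005313, a gene of unknown function with a log2 fold of -1.51 ± 0.31.

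Nucleotide synthesis genes were lower in all 6 tested members, with a median log2 fold of -0.65 (adjusted p = 0.0429, and adjusted p = 0.949 with an estimated correlation). The ribonucleotide reductase subunit CAL0001524 was the 1 member that fell by either adjustment. The genes described as lowered at alkaline pH had a median log2 fold of 0.55 over 14 tested members (adjusted p = 0.0492, and adjusted p = 0.949 with an estimated correlation). Over all genes 1 rose, CAL0003663, a carbamoyl-phosphate synthase subunit, an enzyme that starts arginine and pyrimidine synthesis, at 2.72-fold (log2 fold 1.44 ± 0.30), and 2 rose when adjusted over the list alone. The second was CAL0003777, the catalytic subunit of glucosidase II, which trims sugars on new glycoproteins, at a log2 fold of 1.29 ± 0.31. Over all genes CAL0003777 did not pass (limma adjusted p = 0.0543). It was not well above background in untreated cells, which gives at least 2.05-fold, and without array 1 of the untreated replicate its log2 fold was 0.39 (adjusted p = 0.530), against 2.11 without array 2.

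**Figure D2:**
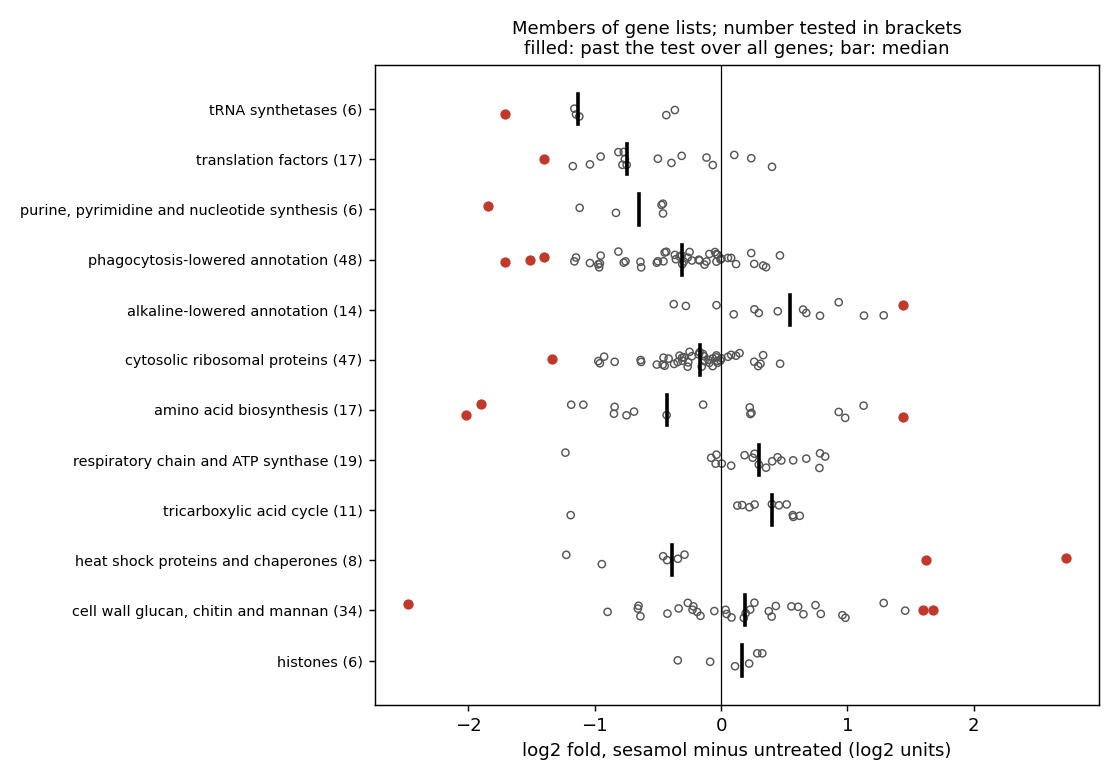
Log2 fold, sesamol minus untreated, of every tested member of 12 gene lists. Circles are genes, filled where the gene passed the test over all genes, the black bar is the list's median, and the number of tested members stands in brackets. The 6 tRNA synthetases all lie left of 0, and the 6 histone genes lie on both sides of 0.

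By camera, quantile normalization in place of the percentile called 0 lists, with 5 at an unadjusted p below 0.05, and leaving out array 1 or array 2 of the untreated replicate also called 0, with 8 and 5. With normexp the translation factors kept a median log2 fold of -0.71 and the phagocytosis list one of -0.47, but both lay above the median of all genes there, so that their direction against other genes turned.

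Repeats of the same preparation lay closer together in the untreated group than in the sesamol group, but with normexp the order turned, with an SD of 1.18 for the untreated pair and 0.47 for the sesamol pair. Over the 960 tested genes, the SD of the log2 difference was 0.38 between the 2 untreated arrays and 0.73 between the 2 arrays of sesamol replicate 2. The single array of sesamol replicate 1 lay 0.65 and 0.49 from these 2 arrays, closer than they lay to each other, so the arrays taken as repeats were not the closest pair among the sesamol arrays. Between preparations, where arrays were averaged first, the SD was 0.44 for the 2 sesamol preparations, 0.74 between the untreated preparation and sesamol replicate 1, and 0.90 between the untreated preparation and sesamol replicate 2. These values were described without a test.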

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

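Cyclic loess and leaving out array 1 of sesamol replicate 2 among single arrays were added after the data were seen. The percentile over all probes was the planned scaling, and the scaling used in its place was chosen after the share of detected probes was seen. All 79 genes kept their direction without array 1 of sesamol replicate 2 and after cyclic loess, but the number of calls moved widely, and the cause was not tested. Against 79, the count was 133 with 5 separate arrays, 601 with the preparation as a random block (correlation -0.755 between arrays of a preparation), 646 with normexp, 122 with quantile normalization, 177 with trend and robust and 164 with the percentile over all probes. Without array 1 of sesamol replicate 2 it was 7 at the level of preparations, and 185 among single arrays, to be set against 133. It was 29 with no filter, 7 with probes detected on all 5 arrays, 9 with outlier spots kept, 10 with the brightest probe, 8 against a 1.5-fold change and 13 with cyclic loess. With quantile normalization, normexp and no filter, the named genes shared the same SE within each setting (0.415, 0.286 and 0.506). Their calls there followed the size of the fold alone. Repeats that share a preparation would give a positive correlation, so the random block with -0.755 did not describe these arrays. That block also cut the SE of CAL0005596 to 0.0926 from 0.301, so the 601 is not a usable count. Leaving out arrays or preparations gave 0 to 295 genes. Shifted lists, 5 at first, numbered 0 with quantile normalization, 3 with median centring, 3 with probes detected on all 5 arrays, 2 with all probes and 3 with cyclic loess. They numbered 0 with fry, and 0 to 7 with arrays or preparations left out. With an estimated correlation they numbered 0, on 1 residual degree of freedom. On 5 separate arrays, with 3, that form of camera gave each of the 5 an adjusted p of 0.934. Normexp called 7 lists, all upward against the other genes, of which 1 was among the 5. The ribosomal protein list, not called at first (adjusted p = 0.151), passed with 5 separate arrays (adjusted p = 0.0388). The limma count of 0 genes without array 2 of sesamol replicate 2 stood beside 127 genes at an unadjusted p below 0.05, and without sesamol replicate 2 among separate arrays beside 336. Normexp moved the SD between the untreated arrays to 1.181 and between the arrays of sesamol replicate 2 to 0.468. With it the sign turned in the log2 fold of CAL0003342 (-0.253), CAL0005613 (-0.784), CAL0006153 (-0.822), CAL0000187 (-0.527), CAL0003777 (-0.975), CAL0005303 (-0.582), CAL0003683 (-0.872), CAL0000985 (-0.795) and CAF0007466 (-0.861), the median of the alkaline-lowered list (-0.137), and the direction of the phagocytosis (adjusted p = 0.546) and translation factor (adjusted p = 0.981) lists. Folds that shrank with it but kept their sign included CAL0004176 (0.798), CAL0005117 (-1.381) and CAL0000988 (-1.318). With the series matrix values the log2 fold of CAL0005556 grew to -3.788. Over all alternatives, normexp included, named genes kept direction and, where there was a test, call in 561 cases. They lost the call in 282, gained it in 31 and turned in sign in 9. No paired analysis was possible because the groups share only 1 number. Signal over background limits the depth: most genes were not detected on any array.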

Other observations

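The tests on the translation lists and on the DNA synthesis genes were chosen after their falls were seen, and those on the 79 genes before, except that the split into measured genes and bounds came after. Energy metabolism gave values without a call. Of 19 tested genes of the respiratory chain and ATP synthase, 15 were higher in sesamol cells, with a median log2 fold of 0.30 (limma camera adjusted p = 0.241), or -0.18 with normexp, and 0 passed by either adjustment. Of 11 tricarboxylic acid cycle genes, 10 were higher, with a median of 0.40 (adjusted p = 0.461), and 0 passed. Glycolysis and fermentation had a median of -0.12 over 8 genes (adjusted p = 0.750). Genes described as induced by stress went both ways, 3 up and 5 down of 44 (adjusted p = 0.841). In the 10 genes of oxidative stress and thiol defence, 1 rose and 1 fell: beside the thioredoxin peroxidase, the putative thioredoxin reductase CAL0000375, which recharges thioredoxin, fell 2.61-fold (log2 fold -1.38 ± 0.31, adjusted p = 0.0446).

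A few further genes were picked out after their values were seen. Besides the transporters already named, the oligopeptide transporter CAL0001200 was at least 2.25-fold lower and a putative spermidine transporter, CAL0005793, at least 1.59-fold lower. A kinase of the osmotic and oxidative stress pathway, the MAPK kinase CAL0004814, fell 2.63-fold and was well above background on 2 of 3 sesamol arrays. Imidazoleglycerol-phosphate dehydratase of histidine synthesis, CAL0003242, was at least 2.69-fold lower. The activator of general amino acid control, CAL0003864, had a log2 fold of -1.32 and did not pass (adjusted p = 0.0614). Among arginine enzymes, beside the carbamoyl-phosphate synthase subunit, argininosuccinate lyase, CAL0004142, stood at 0.93 (adjusted p = 0.107) and CAL0005634 at 0.98 (adjusted p = 0.111).

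The 79 called genes may owe part of their difference to technical causes. Array 1 of sesamol replicate 2 had the lowest 75th percentile of log2 signal over the detected probes, 10.39, although the lowest median signal of detected spots was that of sesamol replicate 1, at 29.6. Without array 1 of sesamol replicate 2 the median log2 fold of the 79 genes was 94.5% of its value. That of the 59 measured in both groups was 92.7%, so their median fold did not rest on that array. Calls favour genes on which the 2 sesamol preparations lie close, and replicate 1 does not hold that array. The test on called genes could therefore hardly have shown that array as the source. The calls still dropped to 7, with the median fold at 3.00 against 3.20 and the prior SD at 0.277 with 4.67 degrees of freedom against 0.263 with 5.74 (why they dropped was not tested). After cyclic loess, which removes trends with brightness, 100% of the 79 genes, and so of the 59, stayed at least 2-fold or kept 0.8 of their fold in the same direction, although 13 were called, on a prior of 4.01 degrees of freedom, and why was not tested. Without array 2 of sesamol replicate 2 the median fold of the 79 genes was 3.44 and the prior SD 0.37. For the 20 genes with only a bound, array 1 and a trend with brightness both stay open as causes, since dim values set their folds. Both also stay open for those of the 59 genes that were well above background on only 1 array of a group. A peculiarity of the untreated cells cannot be told apart from sesamol, since there was 1 untreated preparation, and sesamol itself stays open as the biological explanation.

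The lower tRNA synthetases and translation factors could reflect a trend shared by genes of like brightness. Of 10000 random lists matched on brightness, 0.03% had a median as low as the tRNA synthetases, and 0% one as low as the translation factors, which argues against that. After quantile normalization the translation factors kept 75.1% of their median log2 fold, so a part that depends on the scaling stays open, and no list was called there. A slower growth rate under sesamol, or a different density at harvest, is a hypothesis for both lists that these arrays do not test, since growth was not measured and the harvest density of the untreated cells is not stated.

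Falls of 4 picked genes tied to DNA synthesis may mean fewer cells in S phase, the part of the cycle in which DNA is copied. The fixed list for DNA replication and repair showed no such fall as a group: of 3 tested genes 2 were lower and 1 higher, with a median log2 fold of -0.18, and 1 was called. Only 1 of the 4 belongs to it. The set was put together after its values were seen: dUTP pyrophosphatase, the ribonucleotide reductase subunit, a gene similar to PCNA, the replication clamp, at least 2.49-fold lower, and a gene similar to Msh6p of mismatch repair, at least 2.63-fold lower. Histone transcripts, which peak in S phase, had a median log2 fold of 0.17 over 6 genes, with quartiles of -0.04 and 0.27 (a median of -0.21 with normexp, still above that of all genes), and this argues against fewer such cells as the cause. Cyclic loess left the median log2 fold of the 2 genes measured in both groups at 100.8% of its value, which argues against a trend with brightness for them. For the other 2 genes, which have only a bound, such a trend stays open. A change in the shared control of these genes stays open, and was not tested.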
